A study of Danio rerio with 6 samples.

How the data were processed

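Heads of zebrafish larvae were dissected 5 days after fertilization, 30 larvae per replicate, and the tails served for genotyping, per the labels. The design has 3 WT and 3 pnkp homozygous mutant libraries. Libraries named WT were taken as wild type and those named PN as pnkp mutant, and replicate numbers came from the library names. The sample titles also carry the word exercised and one replicate number for all 6 libraries, which were not used. Whether WT and mutant larvae were siblings is not given in the sources used here.

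Per the labels' protocols, the authors mapped Illumina reads to GRCz11 with Hisat2 2.0.4, counted reads per gene with HTSeq in its intersection-strict mode and tested counts with DESeq2 at a fold change of 2 and an adjusted p of 0.05. The deposited values used here are FPKM, fragments per kilobase of gene length scaled to library depth, in 1 column per library for 38833 genes. The step from counts to FPKM, the annotation release and the use of strand are not given in the sources used here, so overlapping and antisense genes cannot be told apart. In each library FPKM times gene length was a whole multiple of 1 step in 100% of values (tolerance 0.05 of a read), which gave back whole reads per gene up to a scale that the values fix. The rebuilt depth was 11721923, 11853079 and 14455193 reads in WT replicates 1 to 3 and 13456225, 12889172 and 13070761 in mutant replicates 1 to 3. In a gene of 2 kb, 3 reads correspond to 0.104 to 0.128 FPKM, the level below which counting error alone leaves a transcript undetected. Libraries of one genotype differed by more than counting noise (chi-square per degree of freedom 6.89 to 13.4 over genes), so each was counted as its own replicate.

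Genes with a mean of at least 1 FPKM over the 6 libraries were tested (20876 genes). The test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend, two-sided) on log2(FPKM + 1), with genotype as the only term and Benjamini-Hochberg adjustment over all genes tested. The count model planned for a table of counts was not used, because the table holds FPKM. Every log2 fold change is mutant minus WT on the log2(FPKM + 1) scale, which understates changes of low genes, and errors beside log2 fold changes are standard errors. Gene lists, 44 in all with 2007 entries, were fixed before the data were examined; 1955 entries matched a gene, 30 of them through tables of older or alternative symbols. Lists were tested with camera of limma at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with the correlation estimated from the data. A list's members were also counted after adjustment over the list alone.

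Genes named in the text followed a rule fixed beforehand: among genes past the threshold with an assigned symbol, a protein-coding biotype and no overlap between the 3 WT and the 3 mutant values, the 12 largest changes in each direction; pnkp; up to 4 members with the smallest p of each list described; and the 13 protein genes of the mitochondrial genome. The same choice of the largest changes was repeated outside the alternate intervals described below, after the data were seen. Names and positions are those of the deposited table in GRCz11.

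The table also lists 4153 genes on 834 alternate contigs. Such a gene was paired with a primary gene when both had the same protein match, strand and chromosome and lay within 100 kb of each other; 2857 were paired with 2482 primary genes, against 69 pairs with the strand reversed. This pairing, and the fits that add or leave out the copies, were chosen after the data were seen. A copy counted with a slightly different length makes the added FPKM approximate.

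The procedure was tested on simulated data, with negative binomial reads drawn from the real means and depths at 1 dispersion for all genes (0.0109, from the replicates) for 20875 tested genes and 3 libraries per genotype. It recovered 17 of 67 genes changed 1.5-fold, 56 of 67 changed 2-fold and 66 of 66 changed 4-fold, with 15 false calls among 154 (9.74%, above the 5% aimed at). So the adjusted p may understate the share of false calls. The simulation changed far fewer genes than the 5188 of 20876 called in the data, which makes the adjustment stricter. Its recovery may therefore be lower than that in the data. The alternatives were pseudocounts of 0.1 and 0.5, no filter or a mean of at least 5 FPKM, rescaling to TPM, median-of-ratios and quantile scaling, limma without the trend or with a robust prior, protein-coding genes only, the replicate number as a block, limma-voom on the rebuilt reads, an adjusted p of 0.01, leaving out chromosome 15 and leaving out each library. The plots were drawn with matplotlib 3.10.9 in Python 3.11.15.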

Results

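RNA was measured in heads dissected from zebrafish larvae 5 days after fertilization. The comparison was between wild-type (WT) larvae and larvae homozygous for a mutation in pnkp, the gene for polynucleotide kinase 3'-phosphatase, an enzyme that prepares broken DNA ends for ligation. Each genotype had 3 libraries, each made from the pooled heads of 30 larvae, so a replicate is a pool and not a single fish. Depth ranged from 11721923 to 14455193 reads assigned to genes per library. The study's title links loss of pnkp to small heads, seizures, delayed development and mitochondrial dysfunction, and the contrast asks which transcripts differed in the mutant heads.

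The targeted gene, pnkp (chromosome 15, 14163193 to 14194208, GRCz11), was listed at 0 FPKM (fragments per kilobase of gene length scaled to library depth) in each of the 6 libraries, and 7 of the 12 primary genes within 100 kb, pnkp among them, were also at 0 throughout. Reads assigned to a copy of pnkp lay on an alternate haplotype contig that GRCz11 carries for the same interval. The gene model of the copy, at 14178723 to 14193893, has a protein match to mouse PNKP. That copy measured 1.85, 3.67 and 3.54 FPKM in WT replicates 1, 2 and 3, from 47, 95 and 111 reads, and 1.23, 1.23 and 1.28 FPKM in mutant replicates 1, 2 and 3, from 38, 35 and 36 reads. The mean was 3.02 ± 1.01 FPKM in WT and 1.25 ± 0.0289 FPKM in mutant heads (SD, n = 3), and every mutant value was below every WT value (exact permutation p = 0.1, two-sided, the smallest p that 3 against 3 libraries can give). In limma the copy fell by 0.81 ± 0.21 on the log2(FPKM + 1) scale (adjusted p = 0.0245). The adjusted p ranged from 0.00602 to 0.0904 over the alternatives, and the call was lost with no filter on low values and on leaving out WT replicate 2 or 3 or any 1 of the mutant replicates. The type and position of the mutation are not given in the sources used here, so the transcript level checks the labels only in part. Reads that align to both the primary gene and the copy may be missing from these counts. A haplotype difference between the pools, which could also change the reads assigned to the copy, was not tested here.

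Mutant and WT heads differed widely. Of 20876 genes tested with limma, 5188 changed at an adjusted p under 0.05, 2690 higher and 2498 lower in the mutant. At the study's cut-off of at least 2-fold, 1425 changed, 655 higher and 770 lower; limma-voom on reads rebuilt from the FPKM gave 2257, 1159 higher and 1098 lower, so the balance of direction turned. The first principal component held 66.1% of the variance and separated the genotypes. The 3 values of one genotype lay wholly above or below those of the other in 8899 genes, 42.6% of those tested, where chance gives 10%. The 2-fold changes were spread unevenly over the genome. GRCz11 holds alternate contigs, second versions of certain chromosome intervals that differ between zebrafish haplotypes. Among primary genes outside those intervals, 3.82% were called at 2-fold (625 of 16353). The share was 18.004% (332 of 1844) among primary genes inside them and 17.5% (468 of 2679) among genes on the contigs themselves (odds ratio 5.41 for the last 2 classes against the first, Fisher's exact test across genes, two-sided, p = 5.39e-192; genes are not independent replicates). With the FPKM of each contig copy added to its primary gene, 4163 of 19776 genes changed and 955 changed at least 2-fold; with those intervals left out, 3326 and 621 of 16353 did. Leaving out WT replicate 3 gave 3164 changed genes.

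**Figure D1:**
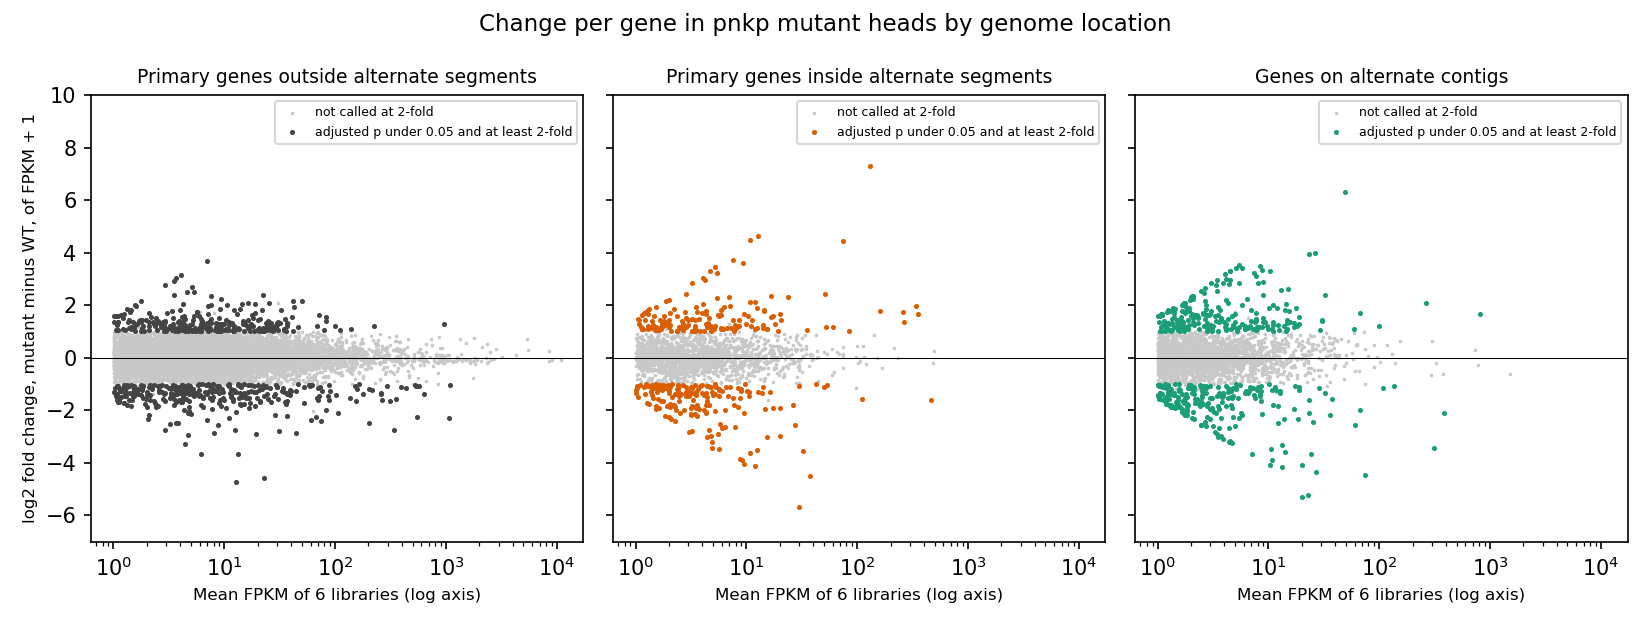
Log2 fold change of FPKM + 1 (mutant minus WT, vertical axis) against the mean FPKM of the 6 libraries (horizontal log axis), 1 point per tested gene, in 3 panels by location in GRCz11. Coloured points, at least 2-fold with an adjusted p under 0.05, make up 3.82% of the genes outside alternate intervals, 18.004% inside them and 17.5% on alternate contigs.

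The 12 largest rises by the rule fixed beforehand were all primary genes in those intervals: apoa1a, nupr1b, crx, h3f3c, gjd1a, tagln2, nfkbib, tppp2, lim2.1, prnpa, lctla and smad6a. The gene apoa1a, for apolipoprotein A-I of plasma lipoproteins (chromosome 5, 37978501 to 37981521), had 0.642 ± 0.265 FPKM in WT and 259 ± 21.3 FPKM in mutant heads (SD, n = 3; log2 fold change 7.31 ± 0.13 SE, adjusted p = 6.87e-08). Its contig copy had 455 ± 31.0 FPKM in WT and 302 ± 87.9 FPKM in mutant heads, and with both added together the log2 fold change was 0.29 (adjusted p = 0.0862). The photoreceptor transcription factor crx (chromosome 5, 36932718 to 36936443) was listed at 0 in every WT library and had 21.7 ± 4.26 FPKM in mutant heads, while its copy had 40.7 ± 2.62 FPKM in WT and 25.2 ± 1.65 FPKM in mutant heads; added together, the log2 fold change was 0.20 (adjusted p = 0.212). Added copies likewise left log2 fold changes of 0.02 for h3f3c, 0.35 for gjd1a, 0.39 for tagln2, 0.03 for nfkbib, -0.14 for lim2.1, 0.24 for lctla and 0.16 for smad6a, none past the threshold, and 0.47 for tppp2 (adjusted p = 0.0258). For nupr1b the sign turned, from 4.63 to -0.68 (adjusted p = 0.0220). No copy was paired with prnpa, which had 0.0569 ± 0.0500 FPKM in WT and 8.002 ± 3.097 FPKM in mutant heads.

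The 12 largest falls were those of ctsba, tefa, cfhl4, eif4g2b, ctsd, ahsg2, hnrnpa0a, aco2, csdc2a, psmb5, mast2 and pdap1a. Of these, ctsba and ahsg2 lay outside the alternate intervals. The gene for the lysosomal protease cathepsin B, ctsba (chromosome 17, 32622931 to 32631514), had 25.4 ± 1.63 FPKM in WT heads (SD, n = 3) and was listed at 0 in each mutant library. Presence in 1 genotype and absence in the other could also come from a haplotype difference at this locus, which was not tested. Cathepsin D, ctsd (chromosome 18), fell by 2.27 with its copy added (adjusted p = 0.00119), against a log2 fold change of -3.85 for the primary gene alone. The primary ctsd gene went from 17.2 to 0.270 FPKM and its copy from 1.63 to 3.09 FPKM. Reads shared between copies or lying on an unpaired copy would be missing from this sum and from those below, which was not tested. The clock-output transcription factor tefa fell by 1.44 (adjusted p = 0.0167) and the RNA-binding protein gene hnrnpa0a by 1.06 (adjusted p = 0.0110) with copies added. For aco2, the mitochondrial aconitase, the primary gene went from 60.4 ± 6.04 to 4.44 ± 2.06 FPKM and the copy the other way, with 31.3 ± 2.59 FPKM in WT and 103 ± 2.04 FPKM in mutant heads; the sum had a log2 fold change of 0.23 (adjusted p = 0.0608). The sum was 0.03 for eif4g2b, 0.02 for csdc2a, 0.19 for mast2 and -0.71 for cfhl4, none past the threshold. It was higher in the mutant for the proteasome subunit psmb5 (0.59, adjusted p = 0.00180) and for pdap1a (0.65, adjusted p = 0.00150).

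**Figure D2:**
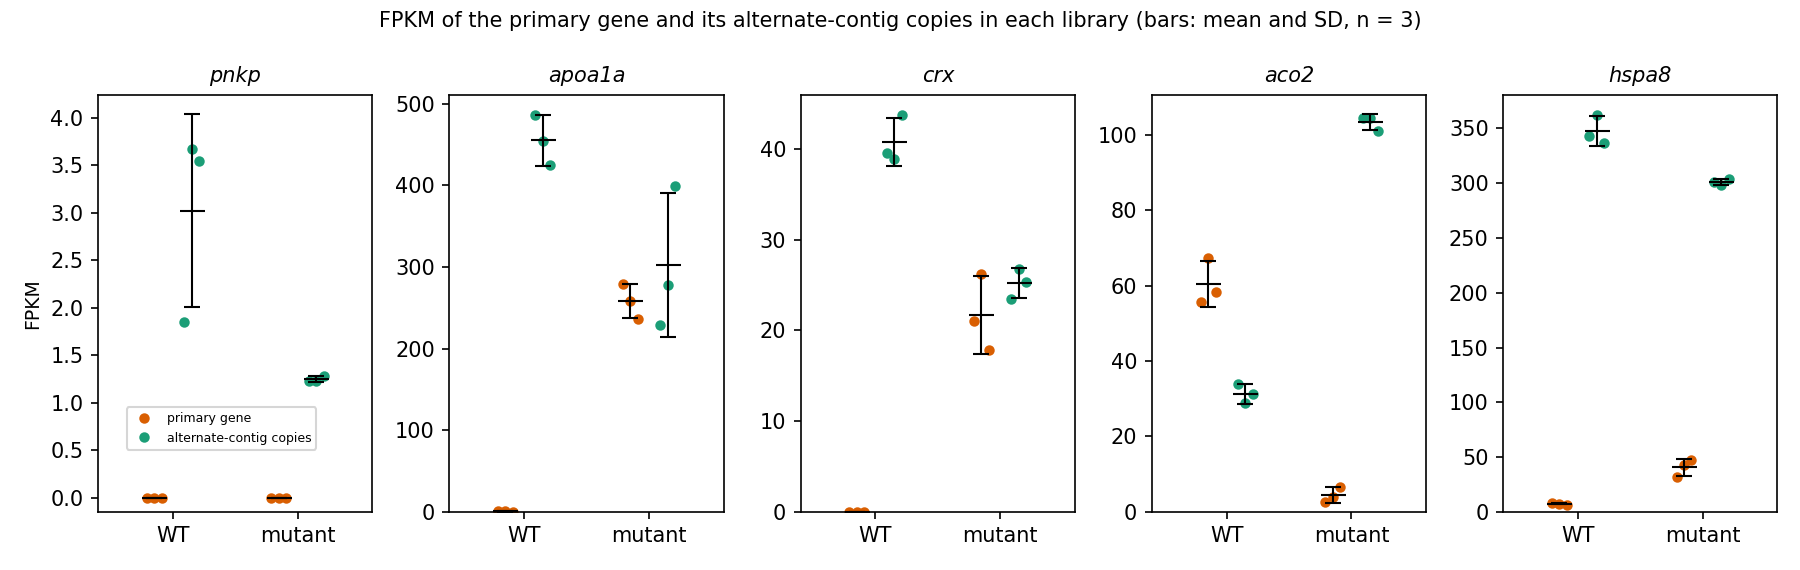
FPKM (vertical axes) in each library of the primary gene (orange) and its alternate-contig copies (green) for pnkp, apoa1a, crx, aco2 and hspa8, in WT and mutant heads; points are libraries, bars the mean and SD of 3. The primary apoa1a gene lies at 0.642 FPKM in WT and 259 in mutant heads while its copy lies between 229 and 487 FPKM in the 6 libraries.

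The same rule applied only outside the alternate intervals, a choice made after the values were seen, named other genes. The 12 largest rises were those of ciapin1, coq9, tcap, ndufb9, mb, tsc22d3, hspb11, mrpl54, pdha1a, pde6ga, col10a1a and mef2ca. The complex I subunit ndufb9 (chromosome 16, 6386941 to 6391275) had 17.8 ± 2.64 FPKM in WT and 83.0 ± 7.79 FPKM in mutant heads (adjusted p = 1.91e-05). The pyruvate dehydrogenase subunit pdha1a rose by 2.02 and coq9, for coenzyme Q synthesis, by 2.499. The iron-sulphur protein assembly factor ciapin1, which lies next to coq9 on chromosome 25, rose by 2.52. WT heads had 0.678 FPKM of coq9 and 0.828 FPKM of ciapin1, against 8.59 and 9.77 FPKM in mutant heads. These neighbours lie on opposite strands, with facing ends at 14398281 and 14398650, so their rises may be 1 local change. A haplotype difference there was not tested. Titin-cap (tcap) rose from 6.51 to 38.0 FPKM, myoglobin (mb) from 14.9 to 68.5 FPKM and the transcription factor mef2ca from 5.46 to 22.1 FPKM. The glucocorticoid-induced gene tsc22d3 rose from 5.60 to 26.9 FPKM, and col10a1a, the collagen of hypertrophic cartilage, from 17.0 to 68.9 FPKM (adjusted p = 0.00308). The 12 largest falls were those of ctsba, ahsg2, cyp24a1, upp2, ucp1, itih3b, ahsg1, cpa5, slc6a17, soul5, dio1 and pde6ha. Among them ucp1, a mitochondrial uncoupling protein, had 588 ± 81.2 FPKM in WT and 86.5 ± 19.4 FPKM in mutant heads (adjusted p = 2.75e-05); cyp24a1, the vitamin D 24-hydroxylase, had 34.8 ± 4.09 FPKM in WT and 3.97 ± 1.52 FPKM in mutant heads (adjusted p = 7.84e-05); and the deiodinase dio1, which activates thyroid hormone, had 18.9 ± 0.661 FPKM in WT and 3.05 ± 0.440 FPKM in mutant heads (adjusted p = 9.83e-06). The cone phosphodiesterase subunit pde6ha fell from 1742 to 379 FPKM and its relative pde6ga rose from 3.39 to 17.9 FPKM.

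Of the 44 gene lists fixed before the data were examined, 13 passed the camera threshold with the preset inter-gene correlation. None did with a correlation estimated from the data. The adjusted p with an estimated correlation was between 0.552 and 0.963 over the 44 lists, and 2 lists had an unadjusted p under 0.05 with it. For the 13 lists the estimate ran from 0.0246 (cell cycle) to 0.538 (liver), above the preset 0.01, so the p values with the preset may overstate the evidence. Of the 10 splits of the 6 libraries into 3 and 3, 5 gave at least 13 lists, the real one included. Among all tested genes 24.9% changed, the share against which counts of list members should be read.

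Of the lists of nuclear-encoded mitochondrial genes, 3 passed, all higher in mutant heads, and those of biogenesis and of the tricarboxylic acid cycle did not. The list of mitochondrial ribosome and translation genes had a median log2 fold change of 0.37 (camera adjusted p = 4.37e-09; adjusted p = 0.552 with an estimated correlation). Of the 70 tested members, 35 rose, 2 fell and 33 did not pass, and with adjustment over the list alone 41 rose and 2 fell. The 4 members with the smallest p were mrpl30 (2.12; 1.36 with its copy added, adjusted p = 0.00139) and mrpl1 (1.92; 0.64, adjusted p = 0.00955), which rose, and mrpl2 (-0.65) and the elongation factor gfm2 (-1.07), which fell. Nuclear subunits of complex I had a median of 0.24 (adjusted p = 0.000541; adjusted p = 0.825 with an estimated correlation). Of the 33 tested members, 10 rose, 3 fell and 20 did not pass, and with adjustment over the list alone 11 rose and 3 fell. Besides ndufb9, the acyl carrier subunit ndufab1b rose (0.55, adjusted p = 0.00628) and ndufs8b fell (-1.18, adjusted p = 0.00789). The gene ndufs8b is listed as a polymorphic pseudogene and was low, at 2.04 FPKM in WT and 0.339 FPKM in mutant heads. Subunits of complexes II to V had a median of 0.23 (adjusted p = 0.000175; adjusted p = 0.825 with an estimated correlation). Of the 47 tested members, 14 rose, 3 fell and 30 did not pass, and with adjustment over the list alone 20 rose and 5 fell. The ATP synthase c-subunit genes atp5mc3a (0.79) and atp5mc1 (0.61), the cytochrome c gene cycsb (0.68) and cox4i1l (1.24) rose.

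The 13 protein genes of the mitochondrial genome did not pass as a list (median 0.11, adjusted p = 0.322; adjusted p = 0.895 with an estimated correlation). Of these 13, mt-atp8 rose (0.60 ± 0.11, adjusted p = 0.00742); adjusted over the list alone the count was the same 1. The other log2 fold changes were 0.40 for mt-nd6, 0.33 for mt-nd1, 0.27 for mt-atp6, 0.23 for mt-nd2, 0.14 for mt-nd5, 0.11 for mt-nd3, 0.11 for mt-cyb, -0.02 for mt-nd4, -0.09 for mt-co1, -0.09 for mt-co2, -0.11 for mt-co3 and -0.20 for mt-nd4l. The short mt-atp8 (8894 to 9058) overlaps mt-atp6, which starts at 9052 and did not pass (adjusted p = 0.159). In WT heads mt-atp8 had 98.7 FPKM and mt-atp6 7658 FPKM. Counting in intersection-strict mode drops reads that reach outside a gene. The mt-atp8 value may thus depend on fragment length as well as on transcript amount. Genes of mitochondrial biogenesis, dynamics and DNA maintenance went both ways (median 0.06, adjusted p = 0.410). Of the 45 tested members, 8 rose, 7 fell and 30 did not pass, and with adjustment over the list alone 10 rose and 7 fell. The kinase pink1 (-1.14) and the ubiquitin ligase prkn (-0.85), which act together in removal of damaged mitochondria, fell, and the prohibitin gene phb rose (0.51, past the threshold in 20 of 21 alternatives). The tricarboxylic acid cycle list did not pass (median 0.18, adjusted p = 0.143). Of the 21 tested members, 6 rose, 4 fell and 11 did not pass, and with adjustment over the list alone 7 rose and 4 fell. Its idh3a rose (0.45, adjusted p = 0.00733), and dlst, 2.41 as a primary gene, was at -0.12 with its copy added (adjusted p = 0.283).

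In the pathway of pnkp itself, the list of single-strand break and base excision repair genes did not pass (median 0.08, adjusted p = 0.322). Of the 23 tested members, 4 rose, 1 fell and 18 did not pass, and with adjustment over the list alone 4 rose and 0 fell. The poly(ADP-ribose) polymerase parp3 had 5.08 ± 1.31 FPKM in WT and 11.4 ± 0.978 FPKM in mutant heads (adjusted p = 0.00291), and the replication clamp pcna rose from 114 to 168 FPKM. The double-strand break repair list did not pass (median 0.08, adjusted p = 0.155). Of the 29 tested members, 4 rose, 0 fell and 25 did not pass, and with adjustment over the list alone 3 rose and 0 fell. Its rpa3 (0.77), h2ax (0.57) and the checkpoint kinase chek1 (0.61) rose, h2ax past the threshold in 19 of 21 and chek1 in 17 of 20 alternatives. The p53 target list did not pass either (median -0.10, adjusted p = 0.665). Of the 30 tested members, 4 rose, 4 fell and 22 did not pass, and with adjustment over the list alone 4 rose and 5 fell. The cell cycle inhibitor cdkn1a had 13.7 ± 3.198 FPKM in WT and 31.2 ± 2.501 FPKM in mutant heads (adjusted p = 0.00165) and the ribonucleotide reductase subunit rrm2b had 1.61 ± 0.0607 FPKM in WT and 6.71 ± 0.428 FPKM in mutant heads (adjusted p = 9.39e-05), while the repair factor ddb2, in an alternate interval with no paired copy (-1.50), and sesn1 (-0.68) fell. Genes of the cell cycle and DNA replication passed (median 0.23, adjusted p = 6.73e-05; adjusted p = 0.552 with an estimated correlation). Of the 65 tested members, 18 rose, 0 fell and 47 did not pass, and with adjustment over the list alone 19 rose and 0 fell. The replicative helicase subunits mcm2 (0.77), mcm3 (0.77) and mcm5 (0.85) and the kinase cdk2 (0.66) rose. Apoptosis genes did not pass as a list (median -0.02, adjusted p = 0.665). Of the 30 tested members, 3 rose, 4 fell and 23 did not pass, and with adjustment over the list alone 3 rose and 6 fell. The largest change among them was in diabloa, for a mitochondrial protein that blocks inhibitors of caspases, which had 47.5 ± 1.91 FPKM in WT and 9.71 ± 0.368 FPKM in mutant heads (adjusted p = 2.97e-06) and lies 0.678 Mb from pnkp on chromosome 15; endog rose (1.27).

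Of the lists of neurons and their signalling, 4 passed, all lower in mutant heads, and the glutamatergic list did not. The list of genes of GABAergic signalling, the main inhibitory transmission of the brain, had a median of -0.40 (adjusted p = 5.39e-06; adjusted p = 0.825 with an estimated correlation). Of the 32 tested members, 0 rose, 14 fell and 18 did not pass, and with adjustment over the list alone 0 rose and 16 fell. The receptor subunits gabra3 (-1.39 ± 0.17), gabrb4 (-0.65) and gabrd (-0.64) and the GABA-degrading transaminase abat (-0.75) fell. Epilepsy-associated ion channels had a median of -0.22 (adjusted p = 0.00345; adjusted p = 0.825 with an estimated correlation). Of the 37 tested members, 0 rose, 9 fell and 28 did not pass, and with adjustment over the list alone 0 rose and 10 fell. The sodium channel subunit scn2b (-0.54), the chloride channel clcn2a (-0.67) and the potassium channel kcnc3a (-0.42) fell, past the threshold in 18 of 20, 19 of 20 and 18 of 21 alternatives. The channel kcnc1b, -1.92 as a primary gene, was at -0.17 with its copy added (adjusted p = 0.317). Genes of the synapse and mature neurons had a median of -0.19 (adjusted p = 0.00303; adjusted p = 0.825 with an estimated correlation). Of the 64 tested members, 1 rose, 10 fell and 53 did not pass, and with adjustment over the list alone 1 rose and 9 fell. The mean of this list, relative to WT, was -0.23, -0.01 and -0.23 in mutant replicates 1 to 3 and -0.04, -0.05 and 0.08 in WT replicates 1 to 3, so mutant replicate 2 lay within the WT range. The synaptic vesicle gene sv2a (-0.73) and the tau gene mapta (-0.49) fell, whereas sypa and stxbp1b, -1.96 and 1.90 as primary genes, were at -0.07 and 0.20 with copies added and passed no threshold there. Neuronal differentiation factors had a median of -0.18 (adjusted p = 0.0401; adjusted p = 0.825 with an estimated correlation). Of the 47 tested members, 0 rose, 5 fell and 42 did not pass, and with adjustment over the list alone 0 rose and 0 fell. Its members sox11a (-0.32) and elavl3 (-0.35) fell, past the threshold in 15 of 21 and 9 of 21 alternatives. This list lost its call, with an adjusted p of up to 0.179, without WT replicate 3 or mutant replicate 1 or 3 (median -0.10 without mutant replicate 3), with a mean FPKM of at least 5 and without the mean-variance trend. Glutamatergic genes did not pass (median -0.24, adjusted p = 0.137), but passed with copies added (median -0.26, adjusted p = 0.00548), without alternate intervals (median -0.27, adjusted p = 0.0178) and without mutant replicate 2 (median -0.29), 3 of 21 alternatives. With an estimated correlation the camera adjusted p of this list was 0.825. Of the 35 tested members, 2 rose, 4 fell and 29 did not pass, and with adjustment over the list alone 2 rose and 3 fell. The vesicular transporter slc17a6b (0.47) rose and the glutaminase glsa (-0.47, past the threshold in 18 of 21 alternatives) fell. Neural stem cell and radial glia genes did not pass (median -0.11, adjusted p = 0.665). Of the 40 tested members, 4 rose, 1 fell and 35 did not pass, and with adjustment over the list alone 4 rose and 1 fell. Its id1 (0.88) and her6 (1.14) rose. Microcephaly genes did not pass (median -0.06, adjusted p = 0.665). Of the 25 tested members, 1 rose, 2 fell and 22 did not pass, and with adjustment over the list alone 1 rose and 2 fell. Asparagine synthetase, asns (1.27), rose and wdfy3 (-0.45, past the threshold in 18 of 21 alternatives) fell.

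Transcripts of tissues other than brain moved with genotype too. Liver and plasma protein genes had a median of -0.98 (adjusted p = 2.95e-12; adjusted p = 0.825 with an estimated correlation). Of the 46 tested members, 2 rose, 30 fell and 14 did not pass, and with adjustment over the list alone 2 rose and 37 fell. The fetuin genes fell: fetub had 893 ± 46.2 FPKM in WT and 192 ± 49.2 FPKM in mutant heads (adjusted p = 9.00e-05), ahsg1 went from 15.7 to 1.83 FPKM and ahsg2 from 25.4 to 1.101 FPKM. Exocrine pancreas and gut genes had a median of -0.65 (adjusted p = 4.50e-06; adjusted p = 0.825 with an estimated correlation). Of the 39 tested members, 1 rose, 22 fell and 16 did not pass, and with adjustment over the list alone 2 rose and 22 fell. Mean changes relative to WT were -0.31, -1.09 and -0.57 in mutant replicates 1 to 3 for this list and -0.55, -1.18 and -0.79 for the liver list, so mutant replicate 2 was the lowest in both. Without it the medians were -0.51 and -0.76. The chitinases chia.1 (-2.12) and chia.2 (-1.37) and the carboxypeptidase cpa5 (-2.49) fell, and agr2, a secretory-cell protein disulphide isomerase also found in mucous cells, rose (1.80). Skeletal muscle genes had a median of 0.57 (adjusted p = 6.29e-12; adjusted p = 0.825 with an estimated correlation). Of the 64 tested members, 38 rose, 1 fell and 25 did not pass, and with adjustment over the list alone 43 rose and 2 fell. Fast troponin T, tnnt3a, had 34.7 ± 6.22 FPKM in WT and 109.6 ± 14.6 FPKM in mutant heads (adjusted p = 0.000179), and caveolin 3, cav3, rose by 1.34. Cartilage, bone and extracellular matrix genes had a median of 0.77 (adjusted p = 7.54e-09; adjusted p = 0.825 with an estimated correlation). Of the 44 tested members, 30 rose, 1 fell and 13 did not pass, and with adjustment over the list alone 33 rose and 1 fell. The main cartilage collagen, col2a1a, had 87.7 ± 17.2 FPKM in WT and 190.2 ± 37.3 FPKM in mutant heads (adjusted p = 0.00331), and the proteoglycan link protein hapln1b rose by 1.28. Heat shock and unfolded protein response genes had a median of 0.61 (adjusted p = 5.21e-09; adjusted p = 0.825 with an estimated correlation). Of the 45 tested members, 25 rose, 2 fell and 18 did not pass, and with adjustment over the list alone 30 rose and 3 fell. The small heat shock genes hspb11 (2.04) and hspb9 (1.83) and hspa4a (1.13) rose, while hspa8, 2.299 as a primary gene, was at -0.05 with its copies added (adjusted p = 0.651). As a measure of trunk tissue in the dissected heads, the summed FPKM of 31 posterior hox genes was 50.9 ± 8.81 in WT and 77.1 ± 4.22 in mutant heads (SD, n = 3; exact permutation p = 0.1, two-sided, the smallest possible).

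**Figure D3:**
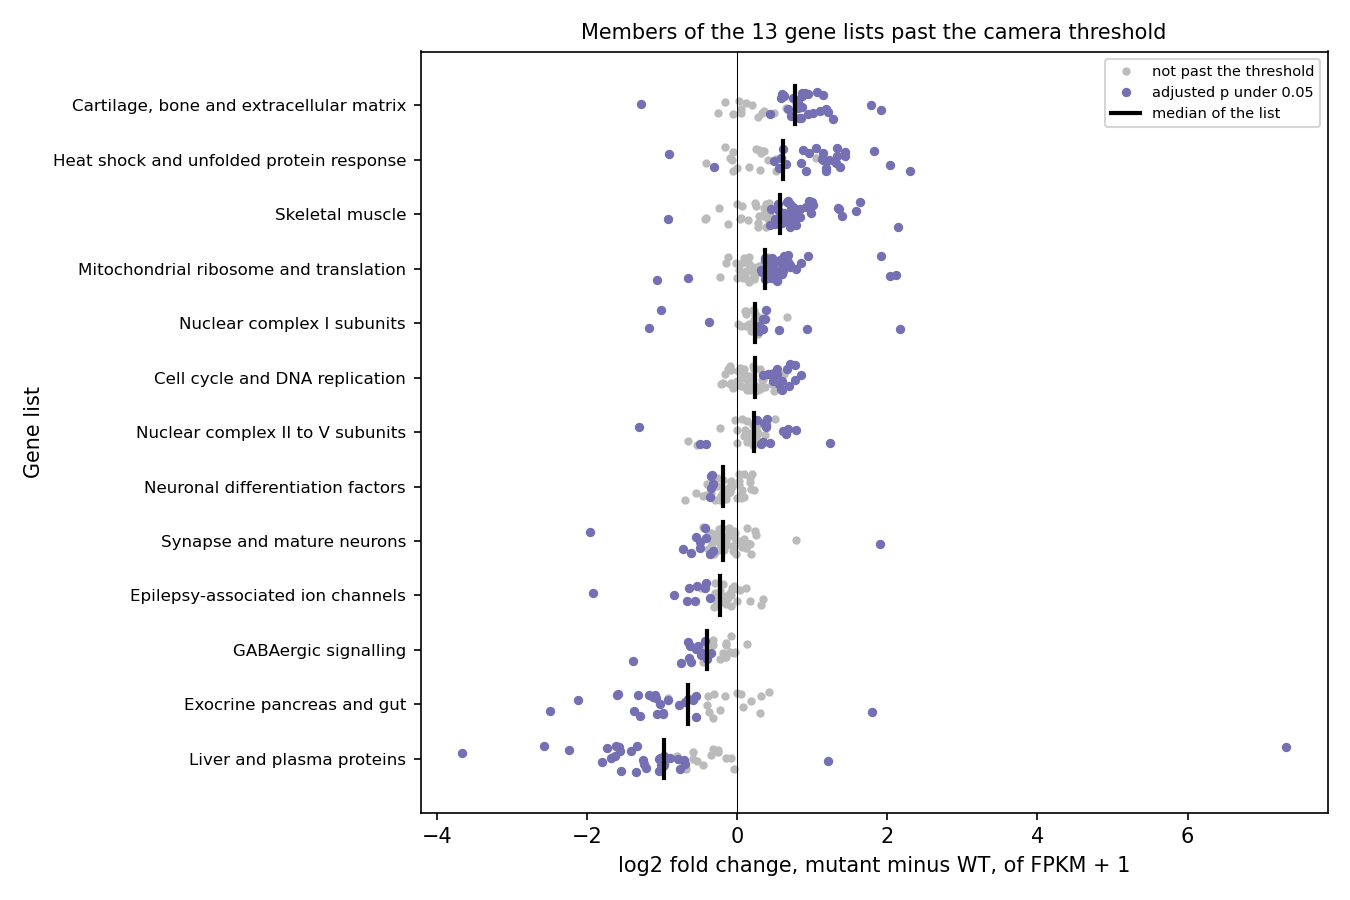
Log2 fold change of FPKM + 1 (mutant minus WT, horizontal axis) of each tested member of the 13 gene lists past the camera threshold, 1 row per list; purple points passed an adjusted p under 0.05, grey points did not, and black bars are medians. Medians run from -0.98 for liver and plasma proteins to 0.77 for cartilage, bone and extracellular matrix.

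The lists of eye and glial cell types did not pass the threshold. Photoreceptor genes had a median of -0.02 and a mean of 0.06, of opposite sign (adjusted p = 0.665). Of the 62 tested members, 17 rose, 12 fell and 33 did not pass, and with adjustment over the list alone 17 rose and 13 fell. The green cone opsin opn1mw1 had 556 ± 63.3 FPKM in WT and 1346 ± 153 FPKM in mutant heads (adjusted p = 0.000245) and the red opsin opn1lw2 rose by 1.98, 1.79 with its copy added; opsins of 1 class are near-identical and share reads, so their split is uncertain. Other retinal cell genes also had a median (-0.04) and mean (0.14) of opposite sign (adjusted p = 0.665). Of the 28 tested members, 7 rose, 2 fell and 19 did not pass, and with adjustment over the list alone 7 rose and 2 fell. The pigment genes tyrp1b (1.196), tyrp1a (1.36) and pmela (1.09) rose and the bipolar cell gene cabp5a (-1.32) fell. Lens genes had a median of -0.06 and a mean of 0.10 (adjusted p = 0.665). Of the 53 tested members, 10 rose, 7 fell and 36 did not pass, and with adjustment over the list alone 12 rose and 8 fell. The crystallins crygm2d1 (1.66) and crygm2d2 (1.75), of a multigene family whose reads cannot be split with certainty, rose; both lie in alternate intervals, crygm2d2 with no paired copy, and 2 of the 10 rises of the list lay outside them. Oligodendrocyte and myelin genes did not pass (median 0.12, -0.05 without alternate intervals, adjusted p = 0.489). Of the 25 tested members, 5 rose, 4 fell and 16 did not pass, and with adjustment over the list alone 5 rose and 4 fell. The myelin genes plp1b (-0.74) and mbpa (-0.48) fell and pmp22b (0.87) rose. Microglia and macrophage genes did not pass (median -0.08, mean 0.00550, adjusted p = 0.665). Of the 17 tested members, 1 rose, 2 fell and 14 did not pass, and with adjustment over the list alone 1 rose and 1 fell. Its grn1 (1.38) rose and apoc1 (-0.62) fell.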

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

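The fits with copies added, without alternate intervals and without the length trend were chosen after the data were seen. The number of changed genes, 5188, was 3269 with a mean of at least 5 FPKM, 2324 at an adjusted p of 0.01 and 3326 without alternate intervals, where fewer genes were tested or a stricter threshold set, and 3164 to 4683 on leaving out each library in turn, with fewer samples. The number changed at least 2-fold, 1425, was 626 with a mean of at least 5 FPKM, 806 with protein-coding genes only and 621 without alternate intervals, where fewer genes were tested. It was 1784 and 2123 with pseudocounts of 0.5 and 0.1, 2199 after rescaling to TPM, which raised all values against the pseudocount (FPKM summed to 449574 to 493380) and let more genes pass the filter (24212), and 2257 with limma-voom (for which the cause was not tested). Of the 13 lists, 0 passed with an estimated correlation, and 12 or 13 in each other alternative; of all lists tested, 12 to 17 passed there. The fall of the pnkp copy, -0.81, was -0.81 with no filter, no longer past the threshold, and -1.04 to -0.68 on leaving out each library; it gave no value with a mean of at least 5 FPKM, protein-coding genes only or no alternate intervals. With copies added, 12 named genes turned sign: nupr1b (-0.68), lim2.1 (-0.14), eif4g2b (0.0321), aco2 (0.23), csdc2a (0.0230), psmb5 (0.59), mast2 (0.19), pdap1a (0.65), dlst (-0.12), hbbe2 (0.39), tie1 (0.62) and hspa8 (-0.0544). Over all other named genes and lists, 156 gene values and 18 list values lost their call under a setting, 22 and 21 gained one, and none of the 13 lists changed the sign of its median, while medians of 12 of the lists that did not pass did so in 1 or more alternatives. With the replicate number as a block (replicate block), 3905 genes changed, 1422 at least 2-fold, and 14 lists passed. Deviations of same-numbered libraries correlated at -0.06, -0.12 and -0.06 across genes, and each library correlated best with one of another number, so the numbers did not pair the libraries. At this depth and replication, changes of 1.5-fold were recovered in 25.4% of simulated genes. Far fewer genes changed in the simulation than were called in the data, so this share may understate recovery in the data.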

Other observations

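The tests of haplotype copies and of mitochondrial content were chosen after their results were seen, and the removal of the length trend after the data were seen. Several further lists fixed beforehand held changed members without passing as lists. Of all 20876 tested genes, 24.9% changed, 2690 higher and 2498 lower, so changed members are common in any list. Circadian clock genes missed the threshold (median -0.31, adjusted p = 0.0590, 2 of 38 members rose and 8 fell, and adjusted over the list alone 2 higher and 8 lower). The median was -0.19 with copies added and -0.18 without alternate intervals (adjusted p = 0.0930 and 0.167), and the adjusted p was 0.825 with an estimated correlation; with the preset one the list passed in 9 of 21 alternatives, among them without WT replicate 2 (median -0.25), without mutant replicate 2 (median -0.32) and without mutant replicate 3 (median -0.33). Among the 21 alternatives its camera adjusted p was highest, 0.188, without mutant replicate 1. The mean of the list relative to WT was -0.75 in that replicate, against -0.31 and -0.25 in mutant replicates 2 and 3. The clock repressor bhlhe41 fell by 2.12 with its copy added and roraa by 0.56. Cholesterol and lipid synthesis genes did not pass (median -0.10, adjusted p = 0.143, 1 of 35 members rose and 8 fell, and adjusted over the list alone 2 higher and 8 lower). The sterol enzyme cyp51 went from 53.5 to 20.1 FPKM and the desaturase fads2 from 41.4 to 14.4 FPKM, both falls past the threshold (adjusted p = 0.00127 and 3.64e-05). Fatty acid oxidation genes did not pass (median -0.04, adjusted p = 0.155, 3 of 36 members rose and 10 fell, and adjusted over the list alone 4 higher and 12 lower). Besides ucp1, the lipid-sensing receptor pparaa fell (-0.66), and the list passed without WT replicate 1 (median -0.11). In the growth factor list (median -0.11, adjusted p = 0.324, 3 of 36 members rose and 5 fell, and adjusted over the list alone 3 higher and 4 lower), the binding protein igfbp1a went from 57.8 to 20.9 FPKM and igfbp1b from 23.8 to 6.26 FPKM, both lower. Glycolysis genes had a median of -0.05 and a mean of 0.05 (adjusted p = 0.898; 10 of 32 members rose and 7 fell; adjusted over the list alone, 10 higher and 7 lower). Lactate dehydrogenase ldha (0.57) and aldoab (0.84) rose and the liver pyruvate kinase pklr (-0.94) fell. Oxidative stress genes went both ways (median -0.01, adjusted p = 0.894, 9 of 40 members rose and 10 fell, and adjusted over the list alone 10 higher and 12 lower), with a median of 0.03 after rescaling to TPM, with prdx2 lower (-0.88) and the mitochondrial thioredoxin txn2 higher (0.74). In the integrated stress response list (median 0.05, adjusted p = 0.382, 5 of 29 members rose and 4 fell, and adjusted over the list alone 8 higher and 5 lower), asns rose (1.27) and atf5a fell (-0.43), and the median was -0.01 without alternate intervals.

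The remaining lists did not pass in the comparison of all 6 libraries either. Epidermis, ionocyte and mucous cell genes (median -0.01, adjusted p = 0.143, 3 of 37 members rose and 11 fell, and adjusted over the list alone 3 higher and 12 lower) held the keratins krt17, from 236 to 75.1 FPKM, and cyt1l, from 478 to 149 FPKM, both lower; keratins are a multigene family whose reads can be shared. This list passed without mutant replicate 1 (median -0.14). Without mutant replicate 2 the median was 0.15 and the camera adjusted p 0.885. The list mean relative to WT was -0.01, -0.47 and -0.14 in mutant replicates 1 to 3. Endothelium and blood vessel genes (median 0.21, adjusted p = 0.132, 8 of 33 members rose and 3 fell, and adjusted over the list alone 11 higher and 3 lower) held pdgfrb (1.04) and egfl7 (0.88), both higher, and tie1 (-1.06; 0.62 with its copy added). The endothelium and blood vessel list passed with copies added (median 0.26, adjusted p = 0.0230), with no filter and without WT replicate 2 (median 0.24), 3 of 21 alternatives. Its camera adjusted p was 0.825 with an estimated correlation. Heart genes (median 0.20, adjusted p = 0.137, 3 of 11 members rose and 0 fell, and adjusted over the list alone 3 higher and 0 lower) held myl4 (1.09) and tnni1b (0.63), both higher. Erythrocyte genes (median -0.06, adjusted p = 0.665, 1 of 19 members rose and 3 fell, and adjusted over the list alone 1 higher and 3 lower) held fech (-2.16) and tspo (-1.05), both lower, sptb (0.49), higher and past the threshold in 14 of 20 alternatives, and hbbe2 (-1.31; 0.39 with its copy added); the list's median was 0.01 with copies added. Pituitary and hypothalamus genes (median -0.20, adjusted p = 0.143, 2 of 28 members rose and 4 fell, and adjusted over the list alone 2 higher and 4 lower) held growth hormone gh1 (1.34), higher, and pcsk1 (-1.05), lower. Activity-induced immediate early genes (median 0.21, adjusted p = 0.142, 5 of 47 members rose and 4 fell, and adjusted over the list alone 5 higher and 3 lower) held jun (0.52), higher, and scg2b (-0.59), lower, and passed without WT replicate 2 (median 0.27) and without mutant replicate 3 (median 0.35). Interferon and inflammatory genes (median 0.11, adjusted p = 0.665, 3 of 16 members rose and 2 fell, and adjusted over the list alone 3 higher and 3 lower) had a median of -0.10 after rescaling to TPM and held nfkbiab (0.64), higher, and isg15 (-1.46), lower. Neutrophil genes (median -0.28, adjusted p = 0.713, 2 of 9 members rose and 2 fell, and adjusted over the list alone 3 higher and 3 lower) had a median of 0.26 after rescaling to TPM and 0.41 with copies added. Among them cpa5 (-2.49), which the pancreas list also holds, and nccrp1 (-0.53) were lower and lect2l (0.53) and srgn (0.67, in an alternate interval with no paired copy) higher, and nccrp1, lect2l and srgn passed in 12 of 21, 15 of 20 and 13 of 19 alternatives. Of cytosolic ribosomal protein genes (median -0.08, adjusted p = 0.142, 0 of 76 members rose and 2 fell, and adjusted over the list alone 0 higher and 2 lower), rps3a, in an alternate interval with no paired copy, fell (-1.11), and rpl5b (-1.63) was at -0.29 with its copy added, and no other member passed. The list itself passed without WT replicate 2 (median -0.13) and without mutant replicate 3 (median -0.15). Without mutant replicate 1 its camera adjusted p was 0.802. List means relative to WT were 0.05, -0.12 and 0.07 in WT replicates 1 to 3. In mutant replicates 1 to 3 they were -0.22, -0.13 and 0.08, so the call depended on the library left out.

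The first pattern weighed was the excess of 2-fold changes where GRCz11 holds an alternate copy. Of 241 primary genes called at 2-fold with a paired copy, 30 (12.4%) kept a 2-fold call in the same direction when the copies were added, and the median absolute log2 change went from 1.41 to 0.38. In 199 of 237 tested pairs (84.0%) the copy moved the opposite way from the primary gene. A candidate explanation for most of these calls is that the WT and mutant pools carried different haplotypes, whose reads aligned to different copies, and not a change of transcript amount. Outside the alternate intervals, 7.53% of genes within 10 Mb of pnkp on chromosome 15 were called at 2-fold (14 of 186, diabloa among them) against 3.78% of all others, a ratio of 1.99 (odds ratio 2.07, 95% interval 1.103 to 3.60, Fisher's exact test p = 0.0180). This ratio lay just under, and the odds ratio just over, the 2 times set beforehand for the ratio, so a haplotype linked to pnkp cannot be told apart from an effect of the mutation for these 14 genes. The 95% interval and p assume independent genes, but 6 of them, all lower, lie together at 20960069 to 21239416, and without this run, singled out after the values were seen, the share was 4.44% (8 of 180) and the ratio 1.18. Primary genes near-absent in 1 genotype also lay on other chromosomes. For crx on chromosome 5 the means were 0 FPKM in WT and 21.7 FPKM in mutant heads. For eif4g2b on chromosome 18 they were 18.7 and 0.195 FPKM. For ctsba on chromosome 17, outside the alternate intervals, they were 25.4 and 0 FPKM. A difference in genetic background between the pools therefore cannot be told apart from an effect of the mutation for other genes and lists either.

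The second pattern was the fall of liver and pancreas genes together with the rise of muscle and cartilage genes. Less trunk tissue in the dissected mutant heads would lower posterior hox transcripts, but their sum was higher in the mutant by 0.61 ± 0.16 (log2, SE), from 801 to 1437 reads per library, and that of 13 anterior hox genes by 0.25 ± 0.10. This argues against a smaller share of trunk as the whole cause. A dissection that differed in its angle, with more trunk muscle and less viscera, stays open, as does an effect of the mutation on liver and pancreas, which was not tested.

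The third pattern was the rise of mitochondrial ribosome genes with the fall of ion channel and synapse genes, short and long genes respectively. Without the trend of log2 fold change on gene length, the GABAergic list kept 97.0% of its median and the mitochondrial ribosome list 98.5% (adjusted p = 5.66e-06 and 6.82e-09), as the trend over all genes outside alternate intervals was small (0.0139 at 1 kb and -0.00927 at 4 kb, on the log2 scale), which argues against length bias as the whole cause. More mitochondria per cell would raise mitochondrially encoded transcripts about as much, if these follow the number of mitochondria. Their mean change lay below that of the mitochondrial ribosome list by 0.26 ± 0.10 (log2, SE, difference -0.26). The number of mitochondria was not measured and each genotype had 3 libraries, so this difference does not decide the question. More muscle, a tissue rich in mitochondria, may account for part of the rise, as the skeletal muscle list rose too (median 0.57), and with it a smaller neuronal share for part of the fall. A smaller neuronal share alone would raise other tissues alike, whereas muscle rose and liver fell (median -0.98). This stays open, as do a shift in growth, with cell cycle genes higher, and a direct effect of the mutation.

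With 3 libraries against 3 there are 10 splits of the 6 libraries, too few for a share under 0.05. The real split gave 5188 changed genes and 1425 at 2-fold, and the highest other split gave 0 of each in limma, with 1 of the 10 splits as high for either count, the real one included. At an unadjusted p under 0.05 the real split gave 8008 genes and the highest other split 771. Every other split mixed the genotypes, so the genotype difference entered its residual error and lowered its gene counts. These contrasts therefore do not show how many genes chance alone would give. For gene lists the real split gave 13 and the highest other split 23, and 5 of the 10 splits gave at least as many, the real one included.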
